A study of Mus musculus with 56 samples.

How the data were processed

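The values were the log2 signals deposited by the authors, 1 table per tissue, for 45101 probe sets of an Affymetrix mouse whole-genome array. The submitters' processing notes name GCRMA and RMA, without a version and without the part that each played. Each tissue had been normalized on its own, and 25.6% to 27.8% of probe sets in colon and 27.4% to 31.1% in jejunum stood at a common floor (log2 2.28 and 2.32). RNA had been taken from whole tissue with TRIzol and then a column. In the tables, 55 columns equalled the value table of the series exactly, and 1 column of the colon table could not be matched to a sample. The values of KO colon 24 h replicate 3 were therefore taken from the value table of the series, and its batch was set by elimination. The 6 columns of group means in the jejunum table equalled means of the array columns. Arrays were assigned to 2 batches by the names of the array files.

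Of the probe sets, 34958 were annotated to 1 gene, 932 to several and 9211 to none, and genes were named only from the first kind, except for the probe sets of the targeted gene. Symbols and neighbours came from the platform annotation and from the mouse assembly GRCm38.p6. Each gene was represented by its probe set with the highest mean, and the 25% of genes with the lowest mean were left out, which left 13643 genes in colon and 13644 in jejunum. Group means were fitted per tissue with limma 3.58.1 in R 4.3.3 over 28 arrays and 6 groups, with eBayes and a mean-variance trend, two-sided, and p-values were adjusted by Benjamini and Hochberg at 0.05 within each comparison. An interaction was the KO change from 0 h minus the WT change from 0 h. Replicates were taken as the labels give them, as different mice.

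Among 33 gene lists fixed before the data were examined, those with at least 5 measured genes were tested with camera in limma at a preset correlation of 0.01, which gave 30 lists in colon and 31 in jejunum, adjusted within each comparison. Each list test was repeated with a correlation estimated from the arrays and with fry. Named genes were chosen by rule before the data were examined. For each comparison they were the 6 largest rises and 6 largest falls among called genes, for responses to radiation only where the values of both groups did not overlap, and up to 4 called members of each called list. A fixed set of genes of the Tweak and damage response pathways was added, and clone, model and accession symbols were not named by rank. Markers of proximal and distal small intestine were chosen after the data were seen, and so were the batch term, the arrays left out as doubted and the position covariate.

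A self-test put known changes into simulated arrays. Each gene was drawn on its own around its WT 0 h mean, with its spread within the real groups. In colon, 46.3%, 85.1% and 92.4% of genes changed by log2 0.5, 1 and 2 were recovered for WT 6 h against 0 h. In jejunum, 32.8%, 64.2% and 92.4% were recovered for KO 24 h against 0 h. The 6 runs made 3 to 9 false calls each. Simulated genes did not vary together and no simulated array stood apart, so these rates do not cover such structure in the real arrays. Expected overlaps between genotypes were computed from the numbers of called genes. Some genes were not reported here.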

Results

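Gene expression was measured on 56 arrays of whole colon and jejunum from wild type (WT) BALB/c mice and from Tweak knockout (KO) mice, at 0, 6 and 24 h after 3 Gy of irradiation. Tweak is a cytokine of the TNF family, encoded by Tnfsf12. The labels do not say whether the 0 h mice were irradiated. In colon the WT groups held 5, 4 and 4 arrays and the KO groups 5, 5 and 5 at 0, 6 and 24 h. In jejunum they held 5, 5 and 4 WT arrays and 5, 4 and 5 KO arrays. The number of arrays limits the precision. All values are log2 signals, a change is the difference of group means ± SE unless named SD, and a gene was called when its limma adjusted p was under 0.05. All WT arrays belonged to 1 batch, and all KO arrays to another except replicate 1 of the KO 0 h group of each tissue. A genotype value adjusted for batch therefore rested on 1 KO array per tissue. For KO changes from 0 h and for interactions, the batch term only leaves out that array, so it is no test of batch there. Colon and jejunum had been normalized separately, so the tissues were not tested against each other.

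The targeted gene was examined first, in every group. Tnfsf12 signal at the probe set annotated to it and to the read-through transcript Tnfsfm13 was 4.18 ± 0.45, 4.19 ± 0.261 and 4.26 ± 0.182 (SD) in WT colon at 0, 6 and 24 h. In KO colon it was 2.52 ± 0.133, 2.49 ± 0.127 and 2.58 ± 0.242 (SD), near the array floor of 2.28. The KO minus WT differences in colon were -1.66 ± 0.161, -1.70 ± 0.171 and -1.68 ± 0.171, with adjusted p = 1.23e-06, 2.56e-06 and 2.76e-06. WT jejunum had 3.42 ± 0.194, 3.07 ± 0.189 and 3.84 ± 0.186 (SD), and KO jejunum 2.59 ± 0.179, 2.57 ± 0.125 and 2.50 ± 0.0461 (SD). Differences in jejunum were -0.83 ± 0.101, -0.50 ± 0.107 and -1.34 ± 0.107, with adjusted p = 0.000107, 0.0259 and 8.07e-08. The 6 h jejunum value was -0.34 with batch as a term (adjusted p = 0.576). It also lost its call without WT 6 h replicate 1 (-0.50), 2 (-0.48) or 5 (-0.50), or without KO 6 h replicate 1 (-0.47), 3 (-0.47) or 4 (-0.49). The other probe set, which also covers Tnfsf13, had no called difference in either tissue (colon 0 h -0.0020 ± 0.138, adjusted p = 1). Tnfrsf12a, the receptor of Tweak, was not called in any comparison (WT colon at 6 h 0.21 ± 0.238, adjusted p = 0.755).

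The first radiation comparison asked which genes changed in WT colon at 6 h (n = 4) against 0 h (n = 5). Of 13643 genes tested, 196 rose and 101 fell. Eda2r, a TNF receptor family gene, rose by 3.71 ± 0.393 (13.1-fold, adjusted p = 2.05e-06). Its WT 0 h values of 2.28 to 3.32 lay near the array floor of 2.28, so the fold is approximate. Ephx1 (3.35 ± 0.403), Ddit4l (3.07 ± 0.372), Mt2 (3.03 ± 0.297), Phlda3 (2.84 ± 0.322) and Ccng1 (2.72 ± 0.311) had the next largest rises. Cdkn1a, a cyclin-dependent kinase inhibitor, rose by 1.32 ± 0.131, the p53 regulator Mdm2 by 1.12 ± 0.13 and the cell death gene Bbc3 by 1.69 ± 0.267. The largest falls were those of Mcm6 (-1.94 ± 0.332, adjusted p = 0.000985), Tcf19 (-1.79 ± 0.264), Uhrf1 (-1.66 ± 0.317), Pclaf (-1.63 ± 0.294), Slfn9 (-1.59 ± 0.314) and Cdc6 (-1.56 ± 0.37), several of them acting in DNA replication. Ascl2, an intestinal stem cell transcription factor, fell by 1.10 ± 0.233. Among fixed lists, 19 of 26 p53 targets rose, 0 fell and 7 were not called over all genes, and 21 rose adjusted over the list alone. Their mean change was 1.22 (adjusted p = 1.97e-41 with a preset correlation, 0.000339 with an estimated correlation). DNA replication genes changed by -0.97 on average, with 17 of 28 lower over all genes and 27 adjusted over the list alone (adjusted p = 2.4e-30, and 0.0798 with an estimated correlation). Fibroblast and matrix genes had 3 of 13 higher, or 10 adjusted over the list alone (adjusted p = 6.34e-09, and 0.227 with an estimated correlation). A further 10 lists, exocrine pancreas genes among them (mean change -1.91), were called with the preset correlation alone. The mean change of exocrine pancreas genes was -0.97 (adjusted p = 0.122) without WT 0 h replicate 2. The 297 called genes became 176 without WT 0 h replicate 1 or WT 6 h replicate 1, 175 without WT 6 h replicate 2, 187 without WT 0 h replicate 3 and 708 without WT 0 h replicate 5. WT 0 h replicate 2 had absorptive enterocyte transcripts at 11.3, against 7.67 to 9.40 in the other arrays of its group.

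The same question at 24 h set 4 WT colon arrays against the 5 at 0 h. There, 379 genes rose and 343 fell. Eda2r (3.06 ± 0.393, adjusted p = 6.48e-05), Ephx1 (2.99 ± 0.403), Psrc1 (2.69 ± 0.342), Ddit4l (2.36 ± 0.372), Phlda3 (2.31 ± 0.322) and Ccng1 (2.11 ± 0.311) had the largest rises. Cps1, a urea cycle enzyme, fell by 2.75 ± 0.579 (adjusted p = 0.00625), followed by Bub1 (-2.23 ± 0.384), Ighv14-2 (-2.19 ± 0.617), Ccnb2 (-2.19 ± 0.4), Cenpa (-2.12 ± 0.317) and Ccna2 (-2.03 ± 0.406). WT 0 h replicate 2 and 3 carried transcripts of proximal small intestine, with means of 6.81 and 4.86 against 3.62 to 3.87 in the other WT 0 h arrays. Their Cps1 signal was 8.53 and 6.12, against 4.93 to 5.23 in the others and 2.93 to 3.97 at 24 h. The size of the Cps1 fall therefore rests in part on these 2 arrays. All 23 mitosis genes fell, over all genes and adjusted over the list alone, by 1.70 on average (adjusted p = 2.02e-29, and 0.101 with an estimated correlation). The proliferation marker Mki67 was among them (-1.99 ± 0.297). Of 26 p53 targets 18 rose, or 20 adjusted over the list alone (mean 0.98, adjusted p = 6.11e-24, and 0.00988 with an estimated correlation). Cholesterol synthesis genes had 10 of 17 lower, or 14 adjusted over the list alone, led by Fdps (-1.38 ± 0.303), and a list adjusted p = 0.101 with an estimated correlation. B cell markers had 4 of 15 lower, or 9 adjusted over the list alone (Cd79b -1.85 ± 0.473), with adjusted p = 0.307 with an estimated correlation. Interferon response genes had 5 of 18 higher, or 11 adjusted over the list alone (Ifit3 1.65 ± 0.385), with adjusted p = 0.339 with an estimated correlation. The total of 722 became 387 without WT 0 h replicate 1, 417 without WT 0 h replicate 3, 1340 without WT 0 h replicate 5, and 418, 327 and 445 without WT 24 h replicate 2, 3 and 5.

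KO colon at 6 h (n = 5) was set against KO colon at 0 h (n = 5) to ask how mice without Tweak responded. In this comparison, 172 genes rose and 30 fell. The largest rises belonged to the skeletal muscle genes Myh8 (4.99 ± 1.02, adjusted p = 0.00907), Myh1 (4.51 ± 1.04), Tnnc2 (4.22 ± 0.933), Ttn (3.26 ± 0.623) and Tnni2 (3.20 ± 0.632), followed by Eda2r (3.04 ± 0.371, adjusted p = 5.22e-05). Myh8 signal was 7.64 ± 1.1 (SD) in the KO 6 h group, 2.65 ± 0.598 at KO 0 h and 2.67 ± 0.67 at KO 24 h. In WT it was 3.92 ± 2.07, 4.73 ± 2.05 and 4.04 ± 2.97 (SD) at 0, 6 and 24 h, with single arrays as high as 6.55, 7.27 and 8.47, so high Myh8 occurred in arrays of both genotypes and also at 0 h. Arhgap20 (-1.54 ± 0.362), Nxpe2 (-1.02 ± 0.227), Dnajb1 (-1.01 ± 0.21), Tmem140 (-0.97 ± 0.222), Banp (-0.89 ± 0.228) and Id3 (-0.67 ± 0.134) fell most. Of these, Arhgap20, Tmem140 and Banp were not called with batch as a term (-1.47, -0.89 and -0.82, adjusted p = 0.0591, 0.0585 and 0.0995). Among p53 targets 19 of 26 rose, or 21 adjusted over the list alone, by 0.92 on average (adjusted p = 4.17e-37, and 0.000703 with an estimated correlation). The change of p53 targets was 1.10 without KO 0 h replicate 3, whose p53 target mean was 7.94 against 7.03 to 7.08 in the other KO 0 h arrays. Cdkn1a rose by 0.63 ± 0.123 and Mdm2 by 0.57 ± 0.123. KO 0 h replicate 3 had Cdkn1a at 11.37 and Mdm2 at 8.11, against 10.49 to 10.82 and 7.32 to 7.61 in the other KO 0 h arrays. These 2 rises are therefore understated as well. Cholesterol synthesis genes had 3 of 17 higher, or 13 adjusted over the list alone (adjusted p = 7.06e-13, and 0.208 with an estimated correlation). Squamous epithelium genes had 0 of 10 called over all genes and 5 higher adjusted over the list alone, with a mean change of 1.55 (adjusted p = 0.353 with an estimated correlation). The sum of 202 became 115, 118 and 100 without KO 0 h replicate 2, 4 and 5, and 129 without KO 6 h replicate 3.

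At 24 h, KO colon (n = 5) had 19 genes higher and 6 lower than KO colon at 0 h (n = 5). Eda2r rose by 2.50 ± 0.371 (adjusted p = 0.0035), Phlda3 by 1.99 ± 0.304, Dglucy by 1.84 ± 0.393, Psrc1 by 1.83 ± 0.322 and Ccng1 by 1.68 ± 0.293. Fat1 and Piezo2 rose by 0.58 ± 0.0892 and 0.58 ± 0.108. Cenpa, a centromere histone, fell by 1.48 ± 0.299 (adjusted p = 0.0334), Gsdmc2 by 1.29 ± 0.247 and Nrep by 0.79 ± 0.162. With batch as a term, which here only leaves out KO 0 h replicate 1, 7 of 12 named genes kept their call and 12 genes were called. Dglucy, Gsdmc2 and Nrep then lost their call (1.81, -1.28 and -0.76, adjusted p = 0.135, 0.0716 and 0.124). Among p53 targets 9 of 26 rose, or 18 adjusted over the list alone, by 0.73 on average (adjusted p = 6.74e-32, and 0.00182 with an estimated correlation). Mitosis genes had 0 of 23 called over all genes and 14 lower adjusted over the list alone (mean -0.80, adjusted p = 6.21e-17, and 0.303 with an estimated correlation). KO 0 h replicate 3 had a p53 target mean of 7.94, against 7.03 to 7.08 in the other 4 arrays of its group. Its Eda2r signal was 5.71, against 2.54 to 3.09 in those 4 arrays. Phlda3 was 8.04 against 5.29 to 5.78, and Ccng1 12.05 against 9.59 to 9.94. This array raised the 0 h means, so the KO rises of these genes are understated and show no weaker response than in WT. The 25 called genes became 12, 4, 140, 7 and 5 without KO 0 h replicate 1, 2, 3, 4 and 5, and 11, 15, 11 and 8 without KO 24 h replicate 2, 3, 4 and 5. Without KO 0 h replicate 3 and WT 0 h replicate 2, an alternative chosen after the data were seen, 147 genes were called.

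Whether KO and WT colon differed at 0 h (n = 5 and 5) was asked next, and 188 genes were higher and 95 lower in KO. Arl2bp (3.32 ± 0.146, adjusted p = 1.47e-14) and Ap1m2 (3.05 ± 0.0992, adjusted p = 3.13e-17) were higher, and Tnfsf13os (-3.61 ± 0.128) and Zhx2 (-2.69 ± 0.137) were lower. These 4 of 24 named genes kept their call with batch as a term. Dlk1 (2.64 ± 0.318), Ceacam12 (1.90 ± 0.401), Qsox1 (1.71 ± 0.259) and Mzb1 (1.33 ± 0.294) did not (1.79, 0.57, 0.71 and 0.81, adjusted p = 0.363, 1, 1 and 1). Nor did Afm (-2.73 ± 0.542), Sfi1 (-2.70 ± 0.342), Cps1 (-2.40 ± 0.546) and Erdr1 (-1.87 ± 0.427), at -3.53, -1.97, -2.64 and -1.99 (adjusted p = 0.251, 0.375, 0.731 and 0.771). Plasma cell markers had 3 of 9 higher in KO, or 5 adjusted over the list alone (mean 0.54, adjusted p = 1.36e-05, and 0.0496 with an estimated correlation). KO 0 h replicate 1, the only KO array of the WT batch, had a plasma cell mean of 7.42, against 6.78 to 7.32 in the WT 0 h arrays. Jchain, the immunoglobulin joining chain, was higher by 0.94 ± 0.177, and by 0.65 with batch as a term, where it was not called (adjusted p = 1). Of the 13 fibroblast and matrix genes 9 were higher, or 12 adjusted over the list alone, by 0.67 on average (adjusted p = 8.52e-16, and 0.0666 with an estimated correlation). Mitosis genes had 0 of 23 called over all genes and 21 lower adjusted over the list alone (mean -0.86, adjusted p = 3.32e-12, and 0.338 with an estimated correlation). In all, 14 genes were called with batch as a term. The 283 genes became 159, 183 and 619 without WT 0 h replicate 1, 3 and 5, and 152, 136, 187 and 174 without KO 0 h replicate 2, 3, 4 and 5. They were 104 without the arrays WT 0 h replicate 2 and KO 0 h replicate 3, where Ceacam12, Mzb1, Afm and Cps1 also lost their call (1.66, 1.22, -2.45 and -1.60, adjusted p = 0.0661, 0.0794, 0.0604 and 0.0969). The p53 target Mdm2, called with all arrays, lost its call there too (0.34, adjusted p = 0.148). KO 0 h replicate 3 had a p53 target mean of 7.94, against 7.03 to 7.08 in the other KO 0 h arrays.

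At 6 h the same genotype question in colon (KO n = 5, WT n = 4) gave 60 genes higher and 60 lower in KO. Dbp, a clock output transcription factor, was higher by 4.81 ± 0.96 (adjusted p = 0.0108), with 9.68 ± 0.563 (SD) in KO and 4.87 ± 0.43 (SD) in WT. Per2 (3.92 ± 0.72), Tef (2.88 ± 0.63) and Per3 (2.62 ± 0.49) were also higher, beside Ap1m2 (3.30 ± 0.105) and Arl2bp (3.13 ± 0.155). Per2 kept its call with batch as a term (adjusted p = 0.0464), and Dbp, Tef and Per3 did not, at 5.64, 4.46 and 4.17 (adjusted p = 0.429, 0.155 and 0.0605). Sfi1 (-3.59 ± 0.362), Afm (-3.11 ± 0.575), Zhx2 (-2.65 ± 0.145), Tnfsf13os (-2.56 ± 0.136), Erdr1 (-2.10 ± 0.453) and Tor3a (-2.03 ± 0.373) had the largest negative differences. With batch as a term Zhx2 and Tnfsf13os kept their call, and Sfi1, Afm, Erdr1 and Tor3a did not, at -2.67, -4.11, -2.25 and -1.13 (adjusted p = 0.129, 0.169, 0.623 and 0.959). Of the 16 circadian clock genes 8 were higher and 0 lower over all genes, or 10 higher and 4 lower adjusted over the list alone (mean 1.25, adjusted p = 8.09e-08, and 0.00563 with an estimated correlation). A further 8 lists were called with the preset correlation alone, and p53 targets were not called (mean -0.06, adjusted p = 0.697). The batch term left 17 genes called. Without WT 6 h replicate 1, 2 or 4 the 120 became 63, 65 and 77, and without KO 6 h replicate 4 they became 75.

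KO colon at 24 h (n = 5) had 36 genes higher and 28 lower than WT (n = 4). Arl2bp (3.09 ± 0.155), Ap1m2 (2.99 ± 0.105), Nr1d1 (2.91 ± 0.584), Pttg1 (2.08 ± 0.176, adjusted p = 2.97e-08), Col1a1 (1.42 ± 0.219) and C1qtnf3 (1.38 ± 0.236) had the largest positive differences. Zhx2 (-2.98 ± 0.145), Sfi1 (-2.93 ± 0.362), Tnfsf13os (-2.11 ± 0.136), Apod (-1.69 ± 0.184), Ces1d (-1.67 ± 0.326) and Pdgfd (-1.64 ± 0.358) had the largest negative ones. With batch as a term 5 of 15 named genes kept their call, among them Pttg1 (adjusted p = 0.00269), which acts in chromosome separation. Nr1d1, Col1a1 and C1qtnf3 did not (0.76, 0.85 and 1.48, adjusted p = 1, 1 and 0.819), nor did Sfi1, Apod, Ces1d and Pdgfd (-2.01, -1.70, -0.29 and -1.55, adjusted p = 1, 0.0896, 1 and 1). Fibroblast and matrix genes were higher by 0.67 on average, 5 of 13 over all genes and 11 adjusted over the list alone (adjusted p = 6.16e-21, and 0.042 with an estimated correlation). Among them Col1a2, a collagen chain, was higher by 1.14 ± 0.167, and by 0.94 with batch as a term, where it was not called (adjusted p = 1). The p53 targets were not called (mean -0.02, adjusted p = 0.778). The 64 called genes became 42 without WT 24 h replicate 2 and 41 without KO 24 h replicate 3, and 9 were called with batch as a term.

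Whether the colon response depended on genotype was tested as an interaction. At 6 h, 3 genes had a positive interaction and 0 a negative one. They were Myh4, a skeletal muscle myosin (1.34 ± 0.189, adjusted p = 0.00285), Primpol (1.07 ± 0.182, adjusted p = 0.0263) and Tnfsf13os (1.05 ± 0.187, adjusted p = 0.0354, and 0.0558 with batch as a term). Myh8, another skeletal muscle myosin gene, was high on single arrays of both genotypes, with 6.55 in WT 0 h replicate 2. At 24 h, Tnfsf13os (1.49 ± 0.187, adjusted p = 0.000319) and Pttg1 (1.42 ± 0.242, adjusted p = 0.0189) had positive interactions, and Apod (-1.41 ± 0.253, adjusted p = 0.0292, and 0.0658 with batch as a term) and Klf10 (-1.004 ± 0.167, adjusted p = 0.0189) negative ones. Tnfsf13os is no evidence of a response that depends on genotype, since its KO means of 2.34, 2.38 and 2.48 at 0, 6 and 24 h lay near the array floor of 2.28 and could not fall, while WT fell from 5.95 to 4.94 and 4.59. Without WT 0 h replicate 2 and KO 0 h replicate 3, Primpol and Tnfsf13os at 6 h (1.02 and 0.94, adjusted p = 0.0738 and 0.0867) and Apod and Klf10 at 24 h (-1.39 and -0.97, adjusted p = 0.0754 and 0.0578) lost their call. No other gene named for colon had a called interaction. In each test no list was called with an estimated correlation, and 15 lists at 6 h and 10 at 24 h were called with the preset correlation alone. The p53 targets had a mean interaction of -0.29 at 6 h (3 of 26 lower adjusted over the list alone, adjusted p = 0.00193, and 0.426 with an estimated correlation). That value was -0.12 (adjusted p = 0.0707) without WT 0 h replicate 2 and KO 0 h replicate 3. The DNA replication genes had 0.77 at 6 h, with 15 of 28 higher adjusted over the list alone (adjusted p = 4.1e-15, and 0.225 with an estimated correlation). Between genotypes, 68 genes rose in both at 6 h where 2.47 would be shared by chance, and 16 at 24 h where 0.528 would be. The number of called interactions at 6 h became 7 and 25 without WT 0 h replicate 2 and 5. It became 1 without WT 0 h replicate 3, WT 6 h replicate 2, 4 or 5, KO 0 h replicate 2, 3 or 4, or KO 6 h replicate 2. The number of called interactions at 24 h became 12, 2 and 1 without WT 24 h replicate 1, 2 and 3, and 1 without KO 0 h replicate 3 or KO 24 h replicate 2.

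**Figure D1:**
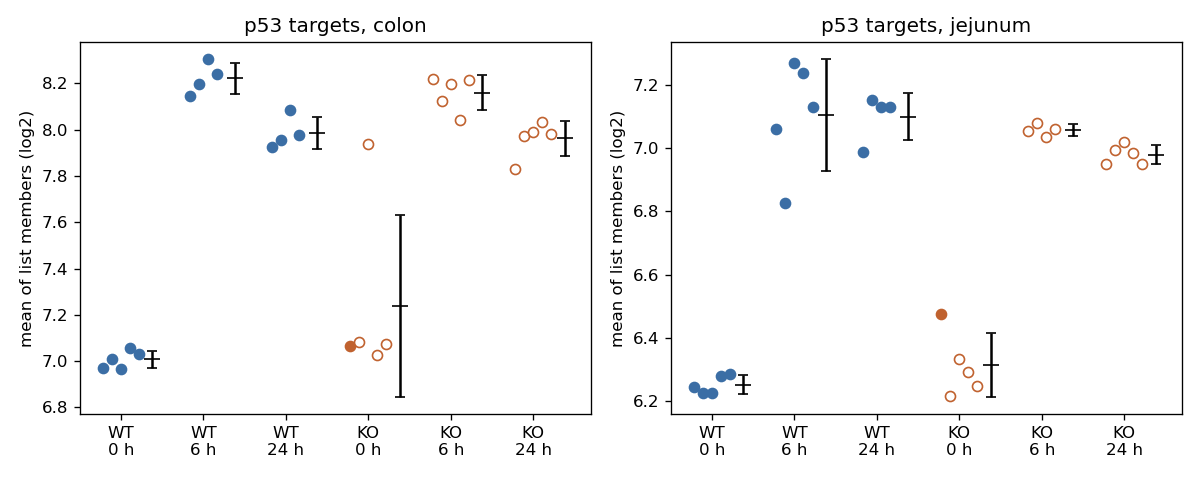
Mean log2 signal of the p53 target list on each array of colon and jejunum, by genotype (blue WT, orange KO) and hours after irradiation. Filled points are arrays of the WT batch and open points arrays of the other batch, bars give the group mean and SD, and colon KO 0 h replicate 3 sits at 7.94, above the 7.03 to 7.08 of its group.

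Jejunum was examined with the same comparisons. WT jejunum at 6 h (n = 5) against 0 h (n = 5) had 36 of 13644 genes higher and 23 lower, and 44 and 15 with quantile normalization. Mt2, a metallothionein, rose by 3.54 ± 0.586 (adjusted p = 0.00207), Phlda3 by 3.17 ± 0.182 (adjusted p = 2.42e-11), Ccng1 by 2.60 ± 0.208, Psrc1 by 2.53 ± 0.218, Ly6e by 2.20 ± 0.403 and Tert by 2.09 ± 0.285. The chaperone gene Hsph1 fell by 2.00 ± 0.407 (adjusted p = 0.0181), Fgf1 by 1.06 ± 0.214, Mllt3 by 0.98 ± 0.192, Dna2 by 0.91 ± 0.21, Shld1 by 0.89 ± 0.176 and Sfrp5 by 0.84 ± 0.14. Dna2 was not called with batch as a term (-0.91, adjusted p = 0.056) or with the proximal minus distal score (-0.86, adjusted p = 0.0542). Bbc3 rose by 1.17 ± 0.195. Of 27 p53 targets 11 rose, or 15 adjusted over the list alone, by 0.85 on average (adjusted p = 6.09e-37, and 1.78e-07 with an estimated correlation). NF-kB and inflammatory genes had a mean change of 0.37 with 0 of 17 called, over all genes or adjusted over the list alone (adjusted p = 7.57e-06, and 0.00258 with an estimated correlation). TWEAK pathway genes had 0.17, with 0 of 9 called (adjusted p = 0.00694, and 0.0515 with an estimated correlation). Stem cell markers had 2 of 16 lower, Aqp4 (-1.50 ± 0.316) and Smoc2 (-0.84 ± 0.156), and a list adjusted p = 0.238 with an estimated correlation. WT 6 h replicate 4 had a mean of 5.46 for proximal and 7.43 for distal small intestinal transcripts, where the WT 0 h arrays had 10.1 to 10.6 and 5.35 to 5.58. The 59 called genes became 34, 38 and 38 without WT 0 h replicate 1, 3 and 4, and 36 and 174 without WT 6 h replicate 2 and 3.

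At 24 h, WT jejunum (n = 4) had 76 genes higher and 115 lower than at 0 h (n = 5). Mbl2 rose by 4.83 ± 0.832 (adjusted p = 0.00255), the chemokine gene Cxcl13 by 3.35 ± 0.599, Psrc1 by 2.91 ± 0.232, Mt2 by 2.88 ± 0.621, Phlda3 by 2.70 ± 0.193 and Egr1 by 2.00 ± 0.278. Paqr9 fell by 2.59 ± 0.453, Olfm4 by 2.54 ± 0.392 (adjusted p = 0.000944), Nusap1 by 2.01 ± 0.325, Far2 by 1.74 ± 0.321, Ccnb2 by 1.73 ± 0.296 and Dmbt1 by 1.61 ± 0.408. Cdkn1a rose by 1.08 ± 0.178. Of 23 mitosis genes 11 fell, or 21 adjusted over the list alone, by 1.06 on average (adjusted p = 1.02e-22, and 0.0911 with an estimated correlation). Mki67 fell by 1.34 ± 0.153. Of 27 p53 targets 11 rose, or 17 adjusted over the list alone, by 0.85 on average (adjusted p = 2.76e-23, and 8.87e-06 with an estimated correlation). A further 4 lists were called with the preset correlation alone. WT 24 h replicate 2 had a proximal mean of 4.89 and a distal mean of 10.8, and replicate 4 a proximal mean of 7.68. With the proximal minus distal score as a covariate Dmbt1 lost its call (-1.26, adjusted p = 0.117). The 191 called genes became 83 and 86 without WT 0 h replicate 3 and 4.

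KO jejunum at 6 h (n = 4) against 0 h (n = 5) had 48 genes higher and 42 lower. Dbp rose by 3.97 ± 0.727 (adjusted p = 0.00729), Phlda3 by 2.90 ± 0.193 (adjusted p = 6.7e-10), Psrc1 by 2.16 ± 0.232, Ccng1 by 2.15 ± 0.221, Plk2 by 2.04 ± 0.194 and Aen by 2.01 ± 0.187. Arntl, a core clock activator, fell by 2.92 ± 0.42 (adjusted p = 0.000436), Hsph1 by 1.81 ± 0.431, Dab1 by 1.44 ± 0.287, Ppargc1b by 1.31 ± 0.312, Tcf19 by 1.21 ± 0.228 and Arrb1 by 1.20 ± 0.244. All 17 named genes kept their call with batch as a term, which here only leaves out KO 0 h replicate 1. With the proximal minus distal score as a covariate Hsph1 (-1.71, adjusted p = 0.0678), Ppargc1b (-0.99, adjusted p = 0.0596) and Slbp (-0.55, adjusted p = 0.0549) lost theirs. Of 27 p53 targets 10 rose, or 15 with 1 lower adjusted over the list alone, by 0.74 on average (adjusted p = 4.84e-25, and 4.94e-06 with an estimated correlation). Circadian clock genes had 4 of 16 higher and 1 lower, or 8 and 3 adjusted over the list alone (mean 0.71, adjusted p = 0.000123, and 0.138 with an estimated correlation). KO 0 h replicate 1 had a clock gene mean of 6.50, against 5.50 to 5.63 in the other arrays of its group. The 4 KO 6 h arrays had proximal means of 5.29 to 5.45, against 9.21, 9.89 and 9.25 in KO 0 h replicate 2, 4 and 5 and 5.32 in replicate 1, so the times also differed in this score. KO 0 h replicate 3 had a proximal mean of 4.53 and a distal mean of 10.4. The 90 called genes became 235, 34, 47 and 30 without KO 0 h replicate 1, 2, 4 and 5, and 44, 40 and 47 without KO 6 h replicate 1, 4 and 5. They were 235 with batch as a term, and 164 without KO 0 h replicate 3 and WT 24 h replicate 2.

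KO jejunum at 24 h (n = 5) had 36 genes higher and 58 lower than at 0 h (n = 5). Mbl2 rose by 5.11 ± 0.784 (adjusted p = 0.00101), Phlda3 by 2.85 ± 0.182, Psrc1 by 2.73 ± 0.218, Ly6e by 2.62 ± 0.403, Plk2 by 1.82 ± 0.182 and Aen by 1.73 ± 0.176. Olfm4, a crypt cell glycoprotein, fell by 2.64 ± 0.37 (adjusted p = 0.000408), Nusap1 by 1.67 ± 0.306, Ccl28 by 1.61 ± 0.335, Csrp2 by 1.60 ± 0.278, Hsd11b2 by 1.49 ± 0.351 and Far2 by 1.41 ± 0.303. All 18 named genes kept their call with batch as a term, which here only leaves out KO 0 h replicate 1 and gave 162 called genes. Of 27 p53 targets 7 rose, or 12 adjusted over the list alone, by 0.67 on average (adjusted p = 2.81e-21, and 1.8e-05 with an estimated correlation). Of 23 mitosis genes 3 fell, or 14 adjusted over the list alone (mean -0.72, adjusted p = 5.32e-14, and 0.164 with an estimated correlation). The mast cell proteases Mcpt1 (-1.90 ± 0.457) and Mcpt2 (-1.33 ± 0.319) fell, 2 of 5 mast cell markers over all genes and the same 2 adjusted over the list alone (list adjusted p = 0.0032, and 0.0466 with an estimated correlation). NF-kB and inflammatory genes (mean 0.30, 0 of 17 called) and TWEAK pathway genes (mean 0.26, 0 of 9 called) both had adjusted p = 0.0379 with an estimated correlation. Proximal means ran from 5.32 to 7.92 in the KO 24 h arrays, and no gene named here lost its call with the position covariate, while Far2 did without KO 0 h replicate 3 and WT 24 h replicate 2 (-1.39, adjusted p = 0.0624). The 94 called genes became 162, 50, 60, 62 and 59 without KO 0 h replicate 1 to 5, and 45, 45, 40 and 60 without KO 24 h replicate 1, 2, 3 and 5.

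**Figure D2:**
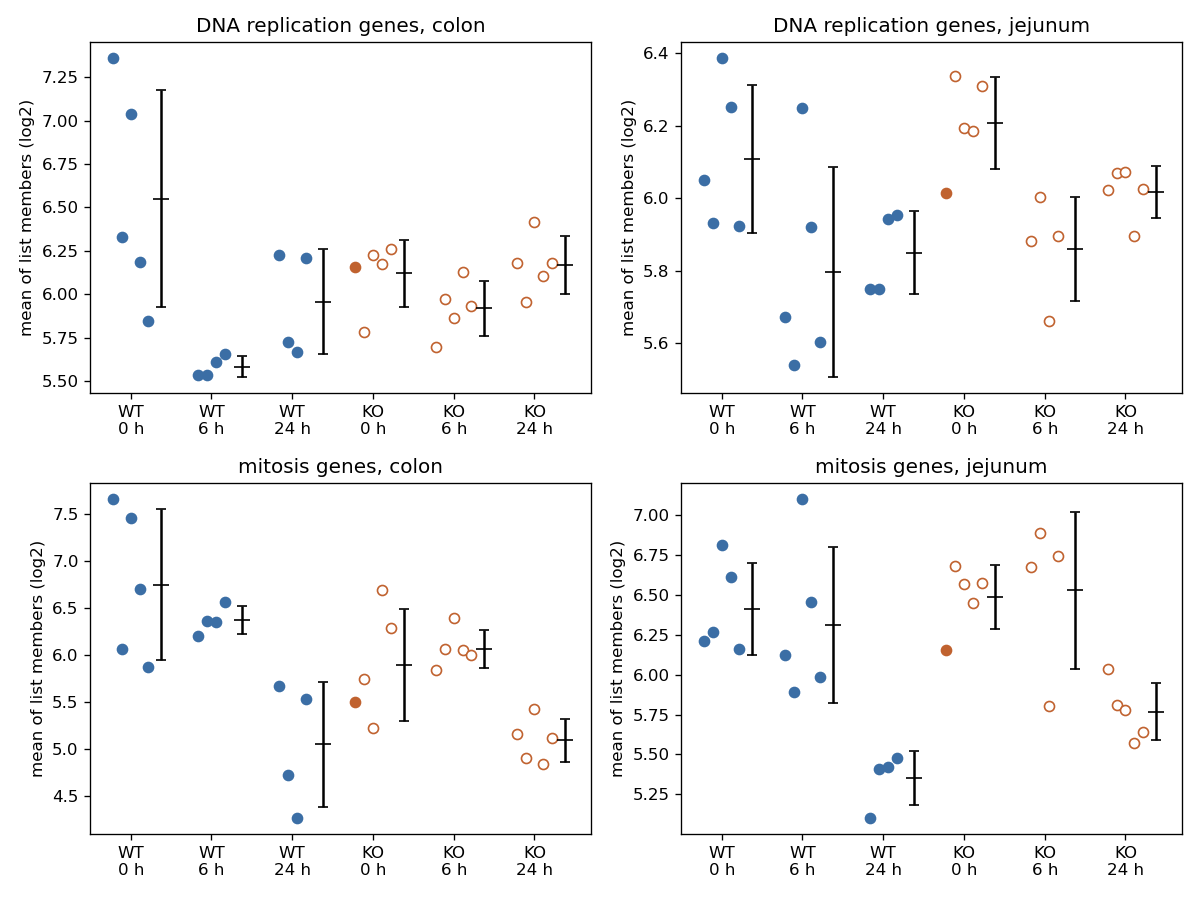
Mean log2 signal of the DNA replication and mitosis lists on each array of colon and jejunum, by genotype (blue WT, orange KO) and hours after irradiation, with the group mean and SD. Filled points are arrays of the WT batch, and the mean change of mitosis genes from 0 to 24 h was -1.70 in WT colon and -1.06 in WT jejunum.

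Genotypes were next compared in jejunum at 0 h (n = 5 and 5), where 8 genes were higher and 17 lower in KO. Ap1m2 (3.82 ± 0.232, adjusted p = 4.6e-11), Arl2bp (3.22 ± 0.23), Lepr (1.43 ± 0.231), Fmo4 (1.38 ± 0.285), Rtf2 (1.08 ± 0.184) and Tfe3 (0.87 ± 0.145) were higher. Tnfsf13os (-4.61 ± 0.386), Cyp1a1 (-3.65 ± 0.559), Zhx2 (-3.01 ± 0.164), Paqr9 (-2.86 ± 0.427), Dnah2 (-2.45 ± 0.446) and Erdr1 (-2.10 ± 0.428) were lower. With batch as a term 6 of 12 named genes kept their call, and Fmo4, Rtf2 and Tfe3 (1.04, 1.00 and 0.85, adjusted p = 0.316, 0.102 and 0.0718) and Cyp1a1, Dnah2 and Erdr1 (-3.25, -2.05 and -2.44, adjusted p = 0.0765, 0.184 and 0.0839) did not. No list was called with an estimated correlation. Fibroblast and matrix genes had 0 of 13 called over all genes and 6 higher adjusted over the list alone (mean 0.63, adjusted p = 1.87e-06, and 0.564 with an estimated correlation). Exocrine pancreas genes had a mean difference of -3.05 (adjusted p = 6.49e-05, and 0.687 with an estimated correlation), and -1.97 without WT 0 h replicate 2. The p53 targets were not called (0.06, adjusted p = 0.927). With the proximal minus distal score as a covariate Fmo4 (1.31, adjusted p = 0.123) and Dnah2 (-1.93, adjusted p = 0.0706) lost their call, and Fmo4 and Erdr1 did without KO 0 h replicate 3 and WT 24 h replicate 2 (1.43 and -2.12, adjusted p = 0.0708 and 0.07). KO 0 h replicate 1 had a proximal mean of 5.32 and a distal mean of 6.42, and replicate 3 had 4.53 and 10.4, against 10.1 to 10.6 and 5.35 to 5.58 in WT. The 25 called genes became 16 without KO 0 h replicate 3. They were 390 with batch as a term, which rests on KO 0 h replicate 1.

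At 6 h, KO jejunum (n = 4) had 190 genes higher and 102 lower than WT (n = 5). The excess of higher genes depended on the scaling, since quantile normalization gave 159 higher and 155 lower. Dbp was higher by 5.40 ± 0.727 (adjusted p = 0.000199), with 9.71 ± 0.153 (SD) in KO and 4.31 ± 0.648 (SD) in WT. Ap1m2 (3.92 ± 0.246), Arl2bp (3.44 ± 0.244), Tef (3.17 ± 0.495), Tns4 (3.14 ± 0.548) and Pmp22 (2.98 ± 0.723) followed. Tff2 and Gkn3, which encode secreted mucosal proteins, were lower by 8.64 ± 2.29 (adjusted p = 0.0455) and 7.93 ± 2.13 (adjusted p = 0.0484), and both belong to the proximal transcripts of the position score. Their KO 6 h values (2.77 to 3.51 and 2.52 to 2.97) lay near the array floor of 2.32, so these sizes are approximate. Tff2 signal was 14.05 ± 0.293, 11.67 ± 4.74 and 9.58 ± 5.69 (SD) in WT at 0, 6 and 24 h, and 8.35 ± 4.96, 3.03 ± 0.338 and 3.71 ± 1.07 (SD) in KO. Tnfsf13os (-4.07 ± 0.409), Car2 (-3.84 ± 1.02), Zhx2 (-3.33 ± 0.174) and Arntl (-2.81 ± 0.42) were also lower. The batch term kept 14 of 18 named calls and gave 744 called genes. Circadian clock genes had 9 of 16 higher and 1 lower, or 11 and 3 adjusted over the list alone (mean 1.22, adjusted p = 4.88e-07, and 0.0541 with an estimated correlation). Interferon response genes had 5 of 18 lower, or 13 adjusted over the list alone (mean -1.16, adjusted p = 7.29e-11, and 0.56 with an estimated correlation). Oasl2, Ifit1, Oas1a and Xaf1 of that list were not called with batch as a term (adjusted p = 0.105, 0.259, 0.0619 and 0.0568), at differences of -2.80, -2.23, -2.49 and -2.45 against -2.45, -2.20, -2.04 and -1.57 without it. WT 6 h replicate 5 had an interferon response mean of 8.34, against 5.81 to 6.45 in the other arrays of its group, and the mean difference of interferon response genes was -0.71 without it. The 4 KO 6 h arrays had proximal means of 5.29 to 5.45 and distal means of 7.30 to 7.88. With the proximal minus distal score as a covariate, an alternative added after the data were seen, 130 genes were called. Tff2 (-2.68, adjusted p = 0.375), Gkn3 (-2.70, adjusted p = 0.441), Car2 (-1.04, adjusted p = 0.28) and Pmp22 (1.34, adjusted p = 0.276) then lost their call, where Tff2 and Gkn3 are part of the score itself. Per2 (2.10, adjusted p = 0.0757) and the interferon response genes Oasl2, Ifit1, Oas1a and Xaf1 (-1.67, -1.30, -1.47 and -0.71, adjusted p = 0.119, 0.292, 0.085 and 0.332) lost theirs as well. Dbp, Tef, Arntl and Nr1d2 kept theirs (4.64, 3.04, -2.66 and 2.38). The 292 called genes became 168, 172, 511 and 170 without WT 6 h replicate 1, 2, 4 and 5, and 134 and 162 without KO 6 h replicate 4 and 5. They were 589 without WT 24 h replicate 2 and KO 0 h replicate 3.

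**Figure D3:**
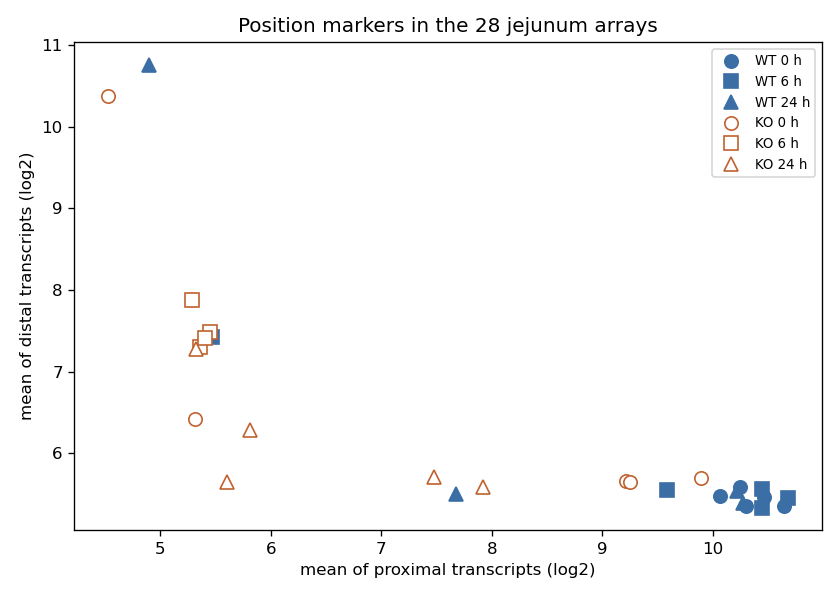
Each of the 28 jejunum arrays by its mean log2 signal of proximal (x axis) and distal (y axis) small intestinal transcripts, with WT in filled blue, KO in open orange, and circles, squares and triangles for 0, 6 and 24 h. The WT 0 h arrays sit at 10.1 to 10.6 on the x axis and the KO 6 h arrays at 5.29 to 5.45.

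KO jejunum at 24 h (n = 5) had 43 genes higher and 53 lower than WT (n = 4). Dbp (4.21 ± 0.727, adjusted p = 0.00351), Nr1d1 (4.09 ± 0.625), Ap1m2 (3.82 ± 0.246), Arl2bp (3.18 ± 0.244), Reg3g (2.89 ± 0.674) and Nr1d2 (2.58 ± 0.43) were higher. Tnfsf13os (-4.04 ± 0.409), Ces1d (-3.77 ± 0.85), Zhx2 (-3.15 ± 0.174), Nfil3 (-2.85 ± 0.459), Angptl4 (-2.63 ± 0.608) and Acot1 (-2.51 ± 0.592) were lower. With batch as a term 8 of 13 named genes kept their call, and Nr1d1 (2.00, adjusted p = 0.589) and Reg3g, an antimicrobial lectin (2.53, adjusted p = 0.531), did not. Nor did Ces1d, Angptl4 and Acot1, at -1.01, -1.64 and -3.50 (adjusted p = 0.916, 0.717 and 0.174). All 14 lists called used the preset correlation alone. Among them, fibroblast and matrix genes had 6 of 13 higher adjusted over the list alone (adjusted p = 0.00063, and 0.517 with an estimated correlation). Exocrine pancreas genes had 8 of 10 lower adjusted over the list alone and differed by -4.24 on average (adjusted p = 2.94e-06, and 0.517 with an estimated correlation), and their array means ranged from 3.53 to 13.46 in jejunum. The 96 called genes became 57, 227 and 52 without WT 24 h replicate 1, 2 and 4, and 38, 45 and 46 without KO 24 h replicate 1, 2 and 3. They were 194 with batch as a term, 271 without WT 24 h replicate 2 and KO 0 h replicate 3, and 203 with the position covariate. Angptl4 lost its call without the arrays WT 24 h replicate 2 and KO 0 h replicate 3 (-2.52, adjusted p = 0.056).

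The jejunum interactions asked whether the response differed between genotypes. With limma, 0 genes were called at 6 h and 0 at 24 h, where 677 and 694 of 13644 had an unadjusted p under 0.05. That is about the 1 in 20 that chance gives. With array weights, 102 and 26 were called. The 6 h count became 13 without KO 0 h replicate 1, which batch as a term also gave, and 1 without WT 6 h replicate 5 or KO 6 h replicate 1. The 24 h count became 6 without WT 24 h replicate 2 and 1 without KO 0 h replicate 2. Circadian clock genes had a mean interaction of 0.99 at 6 h, with 0 of 16 called over all genes and 9 higher and 2 lower adjusted over the list alone (adjusted p = 4.36e-07, and 0.0436 with an estimated correlation). The p53 targets rose in both genotypes, and 20 genes rose in both at 6 h where 0.127 would be shared by chance. At 24 h, 12 genes rose in both and 18 fell in both, where 0.201 and 0.489 would be shared by chance.

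**Figure D4:**
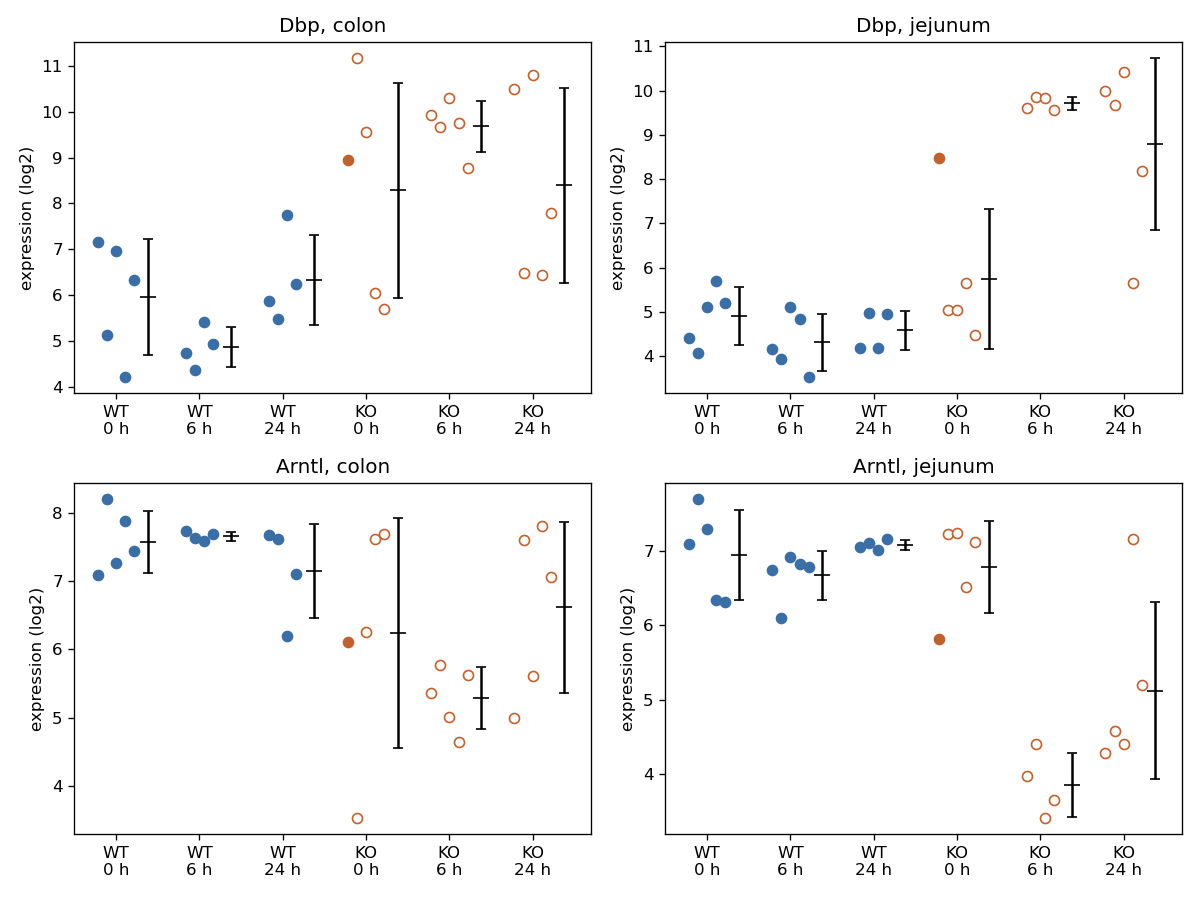
Log2 signal of Dbp and Arntl on each array of colon and jejunum, by genotype (blue WT, orange KO) and hours after irradiation, with the group mean and SD and the arrays of the WT batch filled. In jejunum Dbp averaged 4.31 in WT and 9.71 in KO at 6 h, and Arntl fell from 6.78 to 3.86 in KO.

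Across both tissues and all 3 times, 7 of 12825 genes tested in both tissues had the same called genotype difference. Ap1m2 (2.99 to 3.92), Arl2bp (3.09 to 3.44) and Rtf2 (0.69 to 1.29) were higher in KO each time. Zhx2 (-2.65 to -3.33), Tnfsf13os (-2.11 to -4.61), Tnk1 (-0.80 to -1.24) and Glo1 (-0.68 to -0.91) were lower each time. Ap1m2 encodes a subunit of an epithelial sorting adaptor, and Tnfsf13os lies beside Tnfsf12. TWEAK pathway genes were not called as a list in any colon comparison, and the apoptosis machinery in no comparison of either tissue. The stem cell gene Lgr5 and the cytokine genes Il33 and Cxcl1 had no called change, except that Il33 was called in jejunum KO against WT at 24 h with the position covariate (1.47, adjusted p = 0.0223). Lgr5 lay at 2.61 to 2.68 in WT colon at 24 h, and Cxcl1 lay near 2.57 on most colon arrays. Both are close to the colon floor of 2.28, so the lack of a call there is weak evidence of no change.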

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

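Of the tests in this part, the splits of the samples, the search for a doubly deposited array by its correlation and both uses of the position score were set before their results were seen, and the other tests of patterns A to C were chosen only after.

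Pattern A is a single array. Colon KO 0 h replicate 3 had a p53 target mean of 7.939, within the 7.832 to 8.034 of the KO 24 h arrays and above the 7.026 to 7.081 of the other KO 0 h arrays, and its mitosis mean of 5.22 lay within the KO 24 h range of 4.844 to 5.431. A swap with a KO array of 6 h or 24 h was argued against, since the lowest p53 target mean among those arrays was 7.832 and no partner was out of place. A mislabelled array may explain the pattern and stays open. An array of another sample deposited under a second name was argued against. Its correlation across genes with KO 24 h replicate 1 was 0.9969, above the 0.9962 of any other colon pair, which met the bound set beforehand, but that bound was too weak, since 1 array under 2 names would have equal values in all 13643 genes and only 1051 were equal (median absolute log2 difference 0.0951). No biological explanation was tested for this array.

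Pattern B is the difference between KO and WT jejunum at 6 h. With the proximal minus distal score as a covariate, the log2 differences of 290 called genes kept a median ratio of 0.826, with quartiles of 0.707 and 0.961, and 66 of these genes stayed called. The bound set beforehand to argue against position along the gut was 0.8, which the quartiles span, and the reading was made stricter after this was seen, so that position may explain part of the pattern. With batch as a term the median ratio was 1.35 and 135 genes stayed called, but that term rests on 1 KO array, so batch and genotype cannot be told apart. The genotype itself stays open as an untested biological explanation.

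Pattern C is the difference in clock genes between KO and WT at 6 h in both tissues. Position along the gut was argued against as the whole cause, since Dbp still differed by 4.64 ± 0.797 (limma adjusted p = 0.00342), a ratio of 0.859 to the difference without the score, and Tef, Arntl and Nr1d2 stayed called, while Per2 lost its call (2.10, adjusted p = 0.0757), so that position stays open as a part of the cause. Within groups, clock genes active with Dbp varied against Arntl, Npas2 and Clock across arrays, with r = -0.95 in colon and -0.797 in jejunum (rho = -0.94 and -0.715). The permutation p for r was 1e-05 in each, the smallest that 1e+05 permutations can give, and for rho 1e-05 and 4e-05. Without the 2 farthest arrays r was -0.94 and -0.76. Clock genes thus varied together between arrays of 1 group. Group means were taken out for this test, so it cannot tell why KO and WT differed. A different time of day at collection stays open. The KO 0 h array of the WT batch had Dbp above the WT 0 h range by at least 1.78 in both tissues, but 1 array per tissue leaves batch open. A difference in clock phase by genotype was not tested apart from these.

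Each list mean was tested within each group for an array that stood apart. Of these 366 tests 38 marked an array, where chance marks about 1 in 20, or 18.3. Some arrays were marked for several lists, so the 38 results are not independent. In colon WT 6 h, the marked arrays were replicate 4 for enteroendocrine cell markers (7.03) and replicate 2 for exocrine pancreas genes (4.34). In colon KO 0 h they were replicate 3 for p53 targets (7.94), replicate 2 for DNA replication genes (5.78) and enteric neuron and glia markers (5.95), replicate 4 for endothelial cell markers (5.55) and replicate 5 for exocrine pancreas genes (8.23). Colon KO 6 h replicate 4 stood apart for 6 lists, namely intestinal stem cell (6.15), goblet cell (11.7), plasma cell (7.23) and T and NK cell markers (3.24), NF-kB and inflammatory genes (5.06) and genes beside Tnfsf12 (5.66). Replicate 1 of that group did so for adipocyte genes (7.77). In colon KO 24 h they were replicate 2 for intestinal stem cell markers (6.51) and unfolded protein and heat shock genes (8.61), replicate 4 for NF-kB and inflammatory genes (4.96) and replicate 3 for exocrine pancreas genes (9.67).

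In jejunum WT 6 h, replicate 4 stood apart for tuft cell markers (2.58), T and NK cell markers (3.78) and adipocyte genes (4.36), replicate 3 for mast cell markers (3.39), replicate 1 for smooth muscle markers (8.11) and replicate 5 for interferon response genes (8.34). In WT 24 h these were replicate 1 for p53 targets (6.99) and replicate 2 for tuft cell markers (2.63), MHC class II genes (7.66), cholesterol synthesis genes (8.03) and adipocyte genes (7.30). KO 0 h replicate 3 did so for intestinal stem cell markers (6.56), goblet cell markers (11.3), neutrophil markers (2.33) and cholesterol synthesis genes (8.20), and replicate 1 for smooth muscle markers (9.33) and circadian clock genes (6.50). KO 6 h replicate 4 did so for NF-kB and inflammatory genes (5.40), KO 24 h replicate 4 for DNA replication genes (5.90) and KO 24 h replicate 5 for neutrophil markers (2.51).

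The limma interaction in colon was called for Myh4 (1.338) and Primpol (1.071) at 6 h and for Pttg1 (1.42), Apod (-1.411) and Klf10 (-1.004) at 24 h. Myh4 is a skeletal muscle gene, and Myh8, another, was high on single arrays of both genotypes, also at 0 h. The interaction of Myh4 is therefore not shown to be a response to radiation. Primpol, Apod and Klf10 lost their call without WT 0 h replicate 2 and KO 0 h replicate 3. The interactions of Tnfsf13os (1.047 and 1.494) show no difference in response, since its KO level near the array floor could not fall as the WT level did. Leaving out single arrays left 1 called gene at 6 h in 8 cases and 1 at 24 h in 3 cases. In jejunum the circadian clock genes had a mean interaction of 0.9947 at 6 h. Another 37 list interactions were called with the preset correlation alone.

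Chance was set against each count by 100 splits of the same arrays into groups of the same sizes, the real split included. The bound set beforehand to argue against chance was fewer than 5 of the 100 splits with as many genes. It was not corrected for the number of comparisons, so meeting it does not exclude chance. In colon it was met for WT at 6 h (2 splits gave as many genes, real 297, highest other 907) and 24 h (3, with 722 and 1427), and for KO at 6 h (1, with 202 and 81). It was also met for the genotypes at 0 h (2, with 283 and 348), 6 h (1, with 120 and 63) and 24 h (1, with 64 and 31). The splits do not decide the colon interactions at 6 h (2, with 3 and 3) and 24 h (4, with 4 and 28). Those counts include Tnfsf13os, and genotype was shuffled within each time, which also removed the genotype difference shared by all times. For KO colon at 24 h the bound was not met (6, with 25 and 62). The 0 h group of that comparison holds replicate 3, whose p53 target mean of 7.94 lay within the KO 24 h range. The real count was 140 without that array, so these splits cannot judge the response. In jejunum the bound was met for WT at 6 h (4, with 59 and 980) and 24 h (2, with 191 and 291), for KO at 6 h (4, with 90 and 414) and 24 h (1, with 94 and 59), and for the genotypes at 0 h (3, with 25 and 450) and 6 h (4, with 292 and 420). It was not met for the genotypes at 24 h (5, with 96 and 554). The splits decide nothing for the interactions at 6 h (100, highest other 19) and 24 h (100, highest other 141), because a real count of 0 is reached by any split (limma, with 677 and 694 genes at an unadjusted p under 0.05, about the share that chance gives). Splits that called several times the real count, as for colon WT at 6 h and the colon interaction at 24 h, and for jejunum WT at 6 h, KO at 6 h and the genotypes at 0 h and 24 h, point to a structure of the arrays other than their groups. In those comparisons the count alone does not set the groups apart from that structure. A split by genotype is also nearly a split by batch.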

How the results depend on the processing

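The batch term, the position covariate and the runs without doubted arrays were chosen after the data were seen, and the other alternatives before the data were examined. Counts are totals of called genes, a total is given where it moved by more than 1.5 times, counts of 1 direction are given where they did so under a total that did not (apart from the interactions and the runs without 1 array), and the cause was not tested unless stated. Across all alternatives, named genes kept their side of the threshold in 8579 results, were no longer called in 927 and became called in 43. A change of direction was counted only for called genes, and 0 were found. For lists, 3877 results were kept, 727 were no longer called and 20 reversed. Of the kept list results, 1833 came from leaving out 1 array. With an estimated correlation 164 list results lost their call and 16 kept it, and with fry 140 lost it and 40 kept it.

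With no filter on dim genes, KO colon at 24 h had 15, and in jejunum the lower genes went from 23 to 13 for WT at 6 h and from 102 to 67 and 53 to 35 for KO against WT at 6 and 24 h. With the lowest 50% of genes left out, the colon interactions had 1 at 6 h and 2 at 24 h, and the rises of KO colon at 6 h went from 172 to 108. With all probe sets tested, KO against WT had 106 in colon at 24 h and 42 in jejunum at 0 h, counted in probe sets, and the higher ones at 6 h went from 60 to 91 in colon and from 190 to 291 in jejunum. The mean of probe sets gave 2 for the colon interaction at 24 h. EBayes without trend or with the robust option moved neither a total nor a count of 1 direction by more than 1.5 times. Quantile normalization moved no total, but in jejunum it gave 155 lower genes for KO against WT at 6 h in place of 102, with 159 higher in place of 190, and 15 falls for WT at 6 h in place of 23.

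Array weights in colon gave 640 for WT at 6 h, 503 and 102 for KO at 6 and 24 h, 654 and 129 for KO against WT at 6 and 24 h, and 29 and 7 for the interactions. In jejunum they gave 119 and 1108 for WT at 6 and 24 h, 3615 and 2596 for KO, 82, 1294 and 795 for KO against WT at 0, 6 and 24 h, and 102 and 26 for the interactions. Lists that reversed with array weights were T and NK cell markers in jejunum KO against WT at 0 h (0.071) and, in the 24 h jejunum interaction, goblet cell markers (-0.029) and cholesterol synthesis genes (0.22).

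With only the 2 groups compared in the fit, which leaves fewer arrays, colon had 93 and 65 for WT at 6 and 24 h, 41 and 0 for KO (limma, 1079 genes at an unadjusted p under 0.05 with all groups), and 47 and 31 for KO against WT at 0 and 24 h. Jejunum had 18 and 47 for WT, 22 for KO at 6 h, and 12 and 76 for KO against WT at 0 and 6 h, and at 24 h the falls of KO went from 58 to 91 and the lower genes of KO against WT from 53 to 26. Replicate numbers did not pair the arrays (mean correlation of same numbers 0.0177 in colon and 0.0179 in jejunum, where 10 and 7 of 28 arrays were closest to their own number), and as a block they gave 1 for the colon interaction at 6 h and 50 for KO jejunum at 6 h.

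With batch as a term, colon had 12 for KO at 24 h and 14, 17 and 9 for KO against WT at 0, 6 and 24 h. Jejunum had 235 and 162 for KO at 6 and 24 h, 390, 744 and 194 for KO against WT, and 13 for the interaction at 6 h. Tnfsf12 in jejunum at 6 h became -0.34 (adjusted p = 0.576, and 0.0141 to 0.0368 with the other alternatives that kept all arrays). Reversed lists in colon KO against WT were adipocyte genes at 0 h (-0.17), interferon response genes at 6 h (-0.034) and smooth muscle markers at 24 h (-0.0062). In jejunum these were absorptive enterocyte genes at 0 h (-0.062) and, at 24 h, mitosis genes (0.0020), DNA replication genes (-0.074), T and NK cell markers (-0.23) and smooth muscle markers (0.39).

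Without the doubted arrays (WT 0 h replicate 2 and KO 0 h replicate 3 in colon, WT 24 h replicate 2 and KO 0 h replicate 3 in jejunum), colon had 147 for KO at 24 h, 104 for KO against WT at 0 h and 1 for the interaction at 6 h, the falls of KO at 6 h went from 30 to 46, and the lower genes of KO against WT at 24 h from 28 to 43. Jejunum had 164 for KO at 6 h, 589 and 271 for KO against WT at 6 and 24 h, and 5 for the interaction at 24 h, the falls of WT at 6 h went from 23 to 39, and the lower genes of KO against WT at 0 h from 17 to 11. Cholesterol synthesis genes reversed in jejunum KO against WT at 24 h (0.13, which leaving out WT 24 h replicate 2 alone also gave, and -0.39 without replicate 3) and in the 24 h interaction (0.27), and goblet cell markers in the latter (0.0059). With the position covariate, jejunum had 206 for KO at 24 h, 130 and 203 for KO against WT at 6 and 24 h, and 1 for the interaction at 6 h, and the falls of WT at 6 h went from 23 to 35. Cholesterol synthesis genes reversed in KO at 6 h (-0.080) and in KO against WT at 6 h (-0.27), T and NK cell markers in KO against WT at 0 h (0.044) and 6 h (0.10), and exocrine pancreas genes at 6 h (0.39).

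Leaving out 1 array at a time gave these ranges in colon. WT had 175 to 708 at 6 h and 327 to 1340 at 24 h, and KO had 100 to 246 and 4 to 140. KO against WT had 136 to 619, 63 to 139 and 41 to 67 at 0, 6 and 24 h, and the interactions had 1 to 25 and 1 to 12. Tnfsf12 differences ranged from -1.78 to -1.54, -1.82 to -1.63 and -1.74 to -1.61. In jejunum WT had 34 to 174 and 83 to 235, and KO had 30 to 235 and 40 to 162. KO against WT had 16 to 36, 134 to 511 and 38 to 227, and the interactions had 0 to 13 and 0 to 6 (limma, with 677 and 694 genes at an unadjusted p under 0.05 over all arrays, about the share that chance gives). Tnfsf12 differences ranged from -0.87 to -0.76, -0.57 to -0.44 and -1.40 to -1.26.

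The value table of the series as an alternative equalled the tissue tables in 55 of 55 columns and was not run again, and the tissue difference was not run because the tissues had been normalized separately. Signal over background limits what can be seen near the floor. Il13 and Tslp lay there, and the KO levels of Tnfsf12 and Tnfsf13os lie near it as well. So do Lgr5 and Cxcl1 on most colon arrays, and Eda2r in WT colon at 0 h.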

Other observations

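All tests in this part were chosen after the results were seen.

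Of the 7 genes that differed between KO and WT at all 3 times in both tissues, 2 (Tnfsf13os and Tnk1) were among the 200 tested genes nearest to Tnfsf12 on its chromosome (one-sided Fisher exact p = 0.00483). DNA carried along with the knockout allele may explain these 2. Tnfsf13os lies beside the targeted gene itself, so for it carried DNA cannot be told apart from the targeted change. Without Tnfsf13os the test rests on Tnk1 alone, and it was not run that way. The remaining 5 (Ap1m2, Arl2bp, Rtf2, Zhx2 and Glo1) lay elsewhere, which a background difference between the KO and WT mice could explain. Whether the lines were littermates was not tested.

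The colon and jejunum arrays that share genotype, time and number may come from the same mouse. Their within-group deviations had a mean correlation across genes of 0.122 over 26 shared labels (one-sided permutation p = 0.00043), and 13 of the 26 colon arrays were closest to the jejunum array of their own label. Genes are not independent replicates. The series description calls each array a different mouse.

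In the colon table, 1 column carries a time in its name that no sample of the series has. The column was not read into a comparison, and only its name was used, for the batch of KO colon 24 h replicate 3. Whether its values are those of that array was not checked.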
